A study of Arabidopsis thaliana with 6 samples.

How the data were processed

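Distal leaves were profiled on Affymetrix ATH1 arrays, which are read in 1 colour, with 3 arrays for mock (exudate alone) and 3 for exudate with G3P. Per the labels' protocols, RNA was isolated with Trizol and labelled with biotin, and per the study's design text each replicate came from a separate group of plants. The deposited table holds 1 intensity per probe set and array on a linear scale. Per the submitters' processing notes, the signals came from Affymetrix Expression Console 1.0; the summarization algorithm and the scaling are not given in the sources used here. The 2% trimmed means of 747 to 754 show that the arrays share a level. How the 16129 listed probe sets were chosen is not given either, and the table held 0 control probe sets. Detection calls were not used here.

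Groups were taken from the sample labels. Values were used as deposited, since the array medians of log2(signal + 16) lay within 0.206, under the limit of 0.3 set beforehand. G3P and mock were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend, all 6 arrays in a single fit, no covariates), with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. The pseudocount of 16 understates the change of dim probe sets, and all differences given here are on that scale except the ratios of medians. Those ratios are of signals without a pseudocount. Identifiers, not sequence positions, were used, and no genome build is stated, so no coordinates are given. The study's design text names a rank-sum test for each probe set with the ratio of medians; with 3 against 3 its exact two-sided p cannot go below 0.1, so limma was made the main test and the rank-sum test an alternative.

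Probe sets were named through the platform annotation given with the table: 8950 named 1 gene, 339 named several and were left unnamed, and 6840 had no entry and are unnamed here. Of the single-gene probe sets, 8911 matched an entry of the RefSeq gene table (assembly TAIR10.1), used for current symbols only, and they stood for 8854 genes. For tests of gene lists each gene was represented by its probe set with the highest mean log2 signal.

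Before the data were examined, the following were fixed: the groups, the test, the alternatives, 23 gene lists with 457 members, and the rule for named genes. The rule took, for each direction, 12 probe sets naming a single gene with non-overlapping groups, by size of difference if past the threshold and otherwise by unadjusted p; from each list the up to 4 members with the smallest p; and always PR1, DIR1, AZI1, EARLI1, GLY1, GLI1 and FAD7. It named 68 probe sets. Of the list members 49 had a named probe set, and only these are called measured below. The others could not be looked up, since their probe sets, if present, are unnamed here. Lists with at least 3 measured members were tested with camera (preset correlation 0.01, two-sided), again with an estimated correlation, and with fry, where 0 lists passed after adjustment. After the data had been seen, 29 gene families defined by their symbols were added and tested the same way, because the fixed lists were thin, and the limit of 1 log2 unit for values outside the range of the other arrays was set.

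Alternatives were the replicate number as a block, pseudocounts of 1 and 64, quantile normalization, centring on array medians, leaving out the dimmest 25% or 50% of probe sets, no variance trend, a robust trend, array quality weights, unique probe sets only (15514 of 16129), the rank-sum test, and leaving out each array in turn. The 6 arrays were also split 3 against 3 in all 10 ways.

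The fit was tested on simulated data with the means and spreads of the 16129 probe sets, of which 200 were changed in G3P against mock, in 10 runs. It found 11.8% of those changed by 1 log2 unit, 57.8% at 2, 80.2% at 3 and 89.0% at 4, with a mean of 6.1 false calls a run. In 20 runs with 8854 genes, camera found 100% of lists of 6 genes raised by 2 log2 units and called 10% of unchanged lists at an unadjusted p under 0.05. The lists called in the data (jasmonate, photosynthesis and auxin) had 4, 5 and 3 genes, with mean log2 differences of 1.33, -0.53 and -0.70. These runs therefore give neither the power nor the error rate for those lists. The number of arrays limits the precision of each value.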

Results

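Glycerol-3-phosphate (G3P) is a phosphorylated intermediate of glycerolipid and sugar metabolism, and the series addresses how its delivery to one leaf alters gene expression elsewhere in the plant. Transcript levels were measured in distal leaves of Arabidopsis thaliana, Columbia ecotype, 24 h after a primary leaf had been infiltrated with leaf exudate alone (mock) or with exudate to which G3P had been added. Plants were 3 to 4 weeks old and grew at 22 degrees C, 65% relative humidity and a 14 h photoperiod. Each group had 3 biological replicates, each from a separate set of plants and hybridized to its own ATH1 array. The 6 arrays gave signals for 16129 probe sets, with median signals from 291 on G3P replicate 1 to 338 on mock replicate 1. The 2% trimmed means lay between 747 and 754, so the arrays had been brought to a common level. The number of arrays limits the precision of all comparisons.

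Among genes named by their probe sets, the plastid gene psbK, which encodes a small subunit of photosystem II, had a mean log2 signal of 13.33 ± 0.30 in mock and 11.43 ± 0.66 in G3P leaves (SD, n = 3 each), a log2 difference of -1.91 ± 0.34 (SE). The 20 plastid-encoded photosystem genes, psbK among them, were grouped after the data were seen. Of their differences 8 were positive and 12 negative, with a median of -0.04. The gene psbK was 1 of the 12 named genes in each direction taken by smallest unadjusted p among those with non-overlapping groups, so genes with larger differences can lie outside this set. Among the lower genes of the set, IAA29, which encodes an Aux/IAA repressor of auxin-responsive transcription, had a difference of -1.70 ± 0.42. AT5G25960 (-1.77 ± 0.46) and the metal transporter gene MTPA1 (-1.59 ± 0.39) had signals in G3P leaves near the lowest value the scale allows, so the size of their differences is uncertain. CR4, a receptor kinase of epidermal development, had a log2 difference of -1.35 ± 0.34, and PTI1-4, a kinase gene of the Pto-interacting family, one of -0.82 ± 0.23. The CR4 signals in G3P leaves were also low (5.33 ± 0.39, SD), so the size of its difference is uncertain as well. Among the higher genes of the set, AT4G27300 had a difference of 1.27 ± 0.40, AT3G44450 one of 1.19 ± 0.26 and AT2G24580 one of 1.09 ± 0.33. The AT2G24580 signals were low in mock leaves (5.52 ± 0.14, SD). The plastid gene ndhE, which encodes a subunit of the chloroplast NADH dehydrogenase-like complex, had 9.83 ± 0.24 in mock and 10.58 ± 0.11 in G3P leaves, a difference of 0.76 ± 0.21. None of these genes passed the test across all probe sets (limma, Benjamini-Hochberg adjusted p = 0.912 for each).

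**Figure D1:**
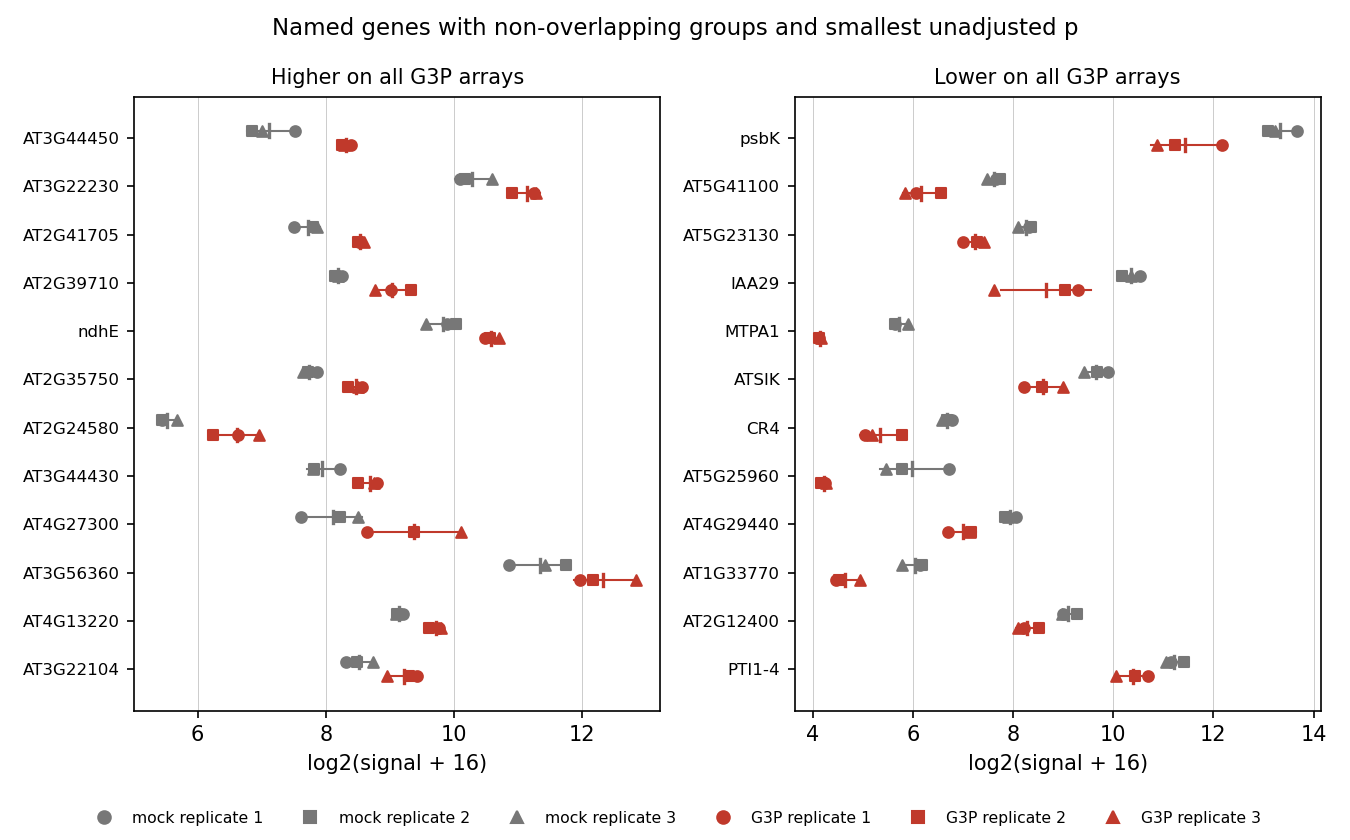
Log2 signal (log2 of signal plus 16, horizontal axis) of the 12 named genes with the smallest unadjusted p in each direction among those whose 3 G3P and 3 mock values do not overlap; symbols are arrays, vertical ticks group means and horizontal lines 1 SD to each side. The psbK values lie at 13.09 to 13.66 in mock and 10.88 to 12.16 in G3P leaves; none of the 24 genes passed after adjustment.

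The other genes named by the same rule had log2 differences of 0.58 (AT4G13220) to 0.98 (AT3G56360) on the higher side, among them AT3G22230, AT2G41705, AT2G39710, AT2G35750, AT3G44430 and AT3G22104. On the lower side they ran from -1.47 (AT5G41100) to -0.81 (AT2G12400), among them AT1G33770, ATSIK, AT5G23130 and AT4G29440. AT1G33770 had 4.64 ± 0.26 (SD) in G3P leaves, near the lowest value the scale allows, so the size of its difference is uncertain. Unadjusted p-values of the 24 genes lay between 0.000555 and 0.0157 in limma.

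Over all 16129 probe sets 0 passed at an adjusted p under 0.05 with limma, 0 higher and 0 lower, and 0 passed with the rank-sum test named in the study's design. The smallest adjusted p was 0.242, for a probe set unnamed here whose mean was 11.40 ± 0.17 in mock and 9.43 ± 0.23 in G3P leaves (SD, n = 3 each), a log2 difference of -1.97 ± 0.21 (SE). At an unadjusted p under 0.05 limma found 496 probe sets, 181 higher and 315 lower, where 806 would be found by chance. After quantile normalization these were 517, 250 higher and 267 lower, and the count was 1196 without G3P replicate 2, 233 without mock replicate 1 and 282 without mock replicate 2. Groups did not overlap for 1393 probe sets (8.64%, with 10% given by chance), 688 of them higher and 705 lower. Of these, 40 were higher and 133 lower by at least 2-fold in the ratio of medians, which is taken without the pseudocount and can be large for dim probe sets. The counts of 40 and 133 were not repeated without dim probe sets. At an unadjusted p under 0.05 the excess of lower probe sets was absent without the dimmest 50% (limma, 119 higher and 108 lower). With 3 arrays against 3 the smallest exact two-sided p of the rank-sum test is 0.1. The 95% interval of the difference lay within 2-fold in either direction for 8481 probe sets (52.6%), so a 2-fold change was not excluded for the remainder. These intervals are not adjusted for the number of probe sets. They are on the scale with the pseudocount, so a 2-fold change in signal is not excluded for dim probe sets among the 8481 either.

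Of the 23 gene lists fixed before the data were examined, 9 had at least 3 members with a named probe set, and 3 of these passed the competitive test with a preset correlation and 0 with an estimated correlation (camera, limma). The jasmonate list was higher in G3P leaves (adjusted p = 0.027), with positive differences for all 4 measured members of 33. The call was lost with an estimated correlation (adjusted p = 0.51). The members were the defensin gene PDF1.2A (1.81 ± 1.01, SE), the thionin gene THI2.1 (0.53 ± 0.49) and the methyltransferase genes JMT (0.93 ± 0.68) and BSMT1 (2.06 ± 1.71), which make methyl jasmonate and methyl salicylate. BSMT1 was near the lowest value the scale allows on all arrays but G3P replicate 3, so the size of its difference is uncertain. The call was also lost without G3P replicate 3 (adjusted p = 0.505), where BSMT1 had a log2 signal of 11.19 against at most 4.56 on the other 5 arrays. Without that array the differences were 0.93 for PDF1.2A, 0.12 for THI2.1, 0.25 for JMT and -0.29 for BSMT1. Without mock replicate 3 the adjusted p was 0.0841 and the difference of JMT 0.40, and PDF1.2A had 0.95 without mock replicate 1 and THI2.1 0.23 without mock replicate 2.

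Photosynthesis genes were lower in G3P leaves (adjusted p = 0.027), with negative differences for all 5 measured members of 31. The call was lost with an estimated correlation (adjusted p = 0.51). RCA, the activase of Rubisco, had a log2 difference of -0.55 ± 0.28 (SE), the antenna protein genes LHCB4.1 and LHCB4.2 had -0.50 ± 0.31 and -0.65 ± 0.44, and the photosystem I gene PSAN had -0.65 ± 0.47. The fifth member, PSBW, chosen after its values were seen, had -0.33 ± 0.32. The adjusted p was 0.418 without G3P replicate 3 and 0.0841 without mock replicate 3. LHCB4.2 and PSAN lay over 1 log2 unit below the range of the other arrays on G3P replicate 3, at 12.80 and 12.43. Without this array the differences were -0.16 for LHCB4.1, -0.08 for LHCB4.2, -0.05 for PSAN and 0.03 for PSBW, and that of RCA was -0.36 without G3P replicate 1.

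The auxin list was lower in G3P leaves (adjusted p = 0.0278), with 2 of 3 measured members negative. This call, too, was lost with an estimated correlation (adjusted p = 0.51). The negative members were IAA29, with the values given above, and GH3.5 (AT4G27260), an auxin-conjugating enzyme. GH3.5 had 8.98 ± 0.81 in mock and 7.55 ± 0.47 in G3P leaves (SD, n = 3 each), a difference of -1.43 ± 0.44 (SE). It stood at 9.89 on mock replicate 3 against at most 8.71 elsewhere, and its difference was -0.97 without that array. IAA29 had a difference of -1.18 without G3P replicate 3. Both genes passed when the limma p was adjusted over the list alone (smallest adjusted p = 0.0117), and neither passed over all probe sets. That adjustment was made within each list separately and takes no account of the other lists, so it is no call across the lists. The related gene GH3.3 had a difference of 1.02 ± 1.18, with 9.68 on G3P replicate 3 against at most 6.88 elsewhere, and -0.35 without that array. The adjusted p of the list was 0.00122 without G3P replicate 3, and the call was lost without G3P replicate 1 (0.223), G3P replicate 2 (0.0774) or mock replicate 3 (0.151).

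**Figure D2:**
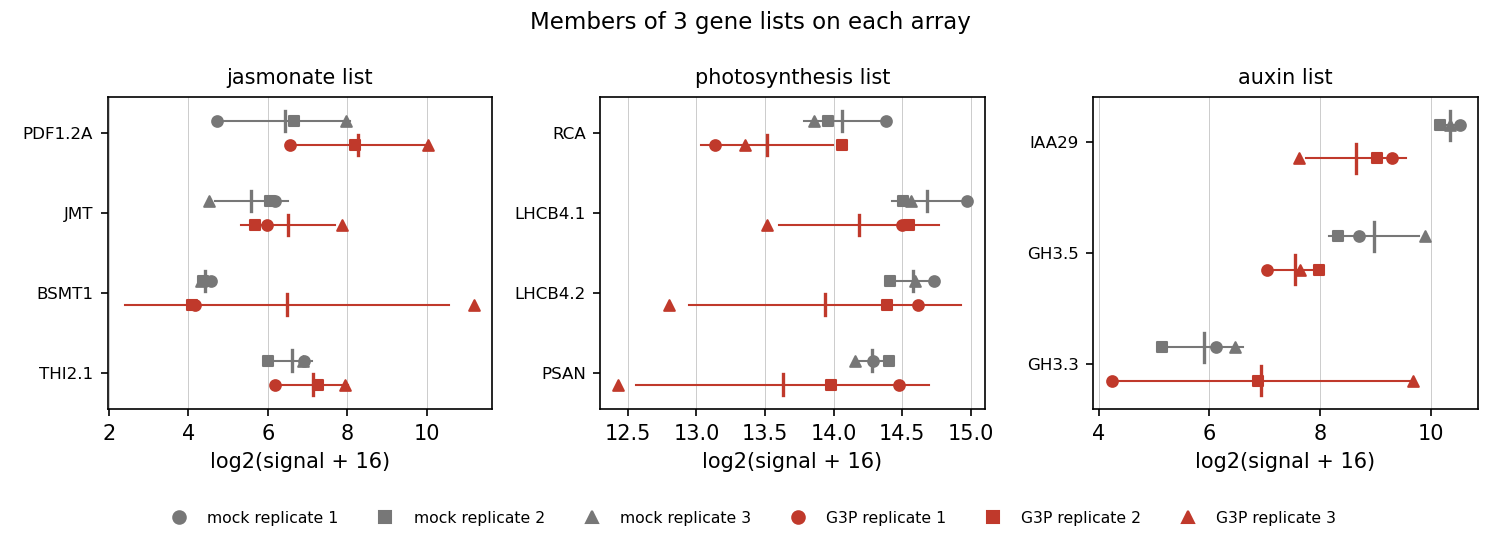
Log2 signal (log2 of signal plus 16, horizontal axes, which differ between panels) of up to 4 members of the jasmonate, photosynthesis and auxin lists on each of the 6 arrays; symbols are arrays, vertical ticks group means and horizontal lines 1 SD to each side. On G3P replicate 3 BSMT1 stands at 11.19, PSAN at 12.43 and IAA29 at 7.62, each over 1 log2 unit outside the range of the other arrays.

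The other 6 tested lists did not pass. Cold and abscisic acid genes had negative differences for all 3 measured members (adjusted p = 0.064), COR47 with -0.64 ± 0.24 (SE), COR15B with -0.61 ± 0.53 and COR15A with -0.26 ± 0.34. This list passed after quantile normalization (adjusted p = 0.0215), with the replicate block (0.0428) and without G3P replicate 1 (0.000342). It gave 0.51 with an estimated correlation, 0.418 without G3P replicate 3, 0.342 without G3P replicate 2 and 0.225 without mock replicate 3. Without G3P replicate 3 the difference of COR15B was 0.04 and that of COR15A -0.03. In the list of salicylic acid and systemic acquired resistance genes 2 of 4 members were positive (adjusted p = 0.711). They were SARD4, an enzyme of pipecolic acid synthesis, with 0.77 ± 0.40, and the glutaredoxin gene GRX480 with 0.60 ± 0.94, while the lectin-like gene LLP1 had -0.57 ± 0.40 and SAG101 had -0.07 ± 0.32. Without G3P replicate 3 these were 0.34 for SARD4, -0.52 for GRX480, -0.10 for LLP1 and -0.33 for SAG101, and SAG101 had 0.20 without G3P replicate 1. Of the G3P metabolism and mobile signal list, 4 of 5 members were negative (adjusted p = 0.634), namely the lipid transfer protein genes DIR1-like (-0.82 ± 0.97) and AZI3 (-0.47 ± 0.76) and the G3P dehydrogenase genes GPDHC1 (-0.31 ± 0.60) and GPDHP (-0.29 ± 0.44). Without G3P replicate 3, the differences of DIR1-like, GPDHC1 and GPDHP were 0.47, 0.48 and 0.20, and that of AZI3 was 0.39 without mock replicate 3. GPDHC2 (AT3G07690), the fifth member and named after its values were seen, had a difference of 0.02 ± 0.25, and -0.10 without mock replicate 3.

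Pattern-triggered immunity genes were mixed, with 2 of 6 positive (adjusted p = 0.715). WRKY6 had a difference of 0.52 ± 0.59, ZAT10 of 0.57 ± 0.85, WRKY22 of -0.23 ± 0.35 and WRKY53 of -0.18 ± 0.84. Each of these directions turned with 1 array left out, to -0.15 for WRKY6 without G3P replicate 3, -0.017 for ZAT10 without mock replicate 1, 0.033 for WRKY22 without G3P replicate 2 and 0.37 for WRKY53 without G3P replicate 1. For this list the median of the members, -0.05, and their mean, 0.10, differed in sign, and the test gave the direction of the mean. Of the cell cycle genes, MCM7 had -1.01 ± 0.56, AUR1 0.44 ± 0.30 and AUR2 0.48 ± 0.64 (adjusted p = 0.715), with a median of 0.44 and a mean of -0.03, and the test gave the direction of the median. AUR2 had -0.16 without mock replicate 3, AUR1 0.22 without G3P replicate 2 and MCM7 -0.63 without G3P replicate 1. The reference genes TIP41, SAND and UBC21 had 0.42 ± 0.21, -0.19 ± 0.23 and 0.01 ± 0.21 (adjusted p = 0.683), and that of UBC21 was -0.025 after quantile normalization. SAND had -0.01 without G3P replicate 3 and UBC21 -0.14 without G3P replicate 1.

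The remaining 14 lists had fewer than 3 measured members and were not tested as lists. The clock gene GI had a difference of -1.18 ± 0.67, with 6.91 on G3P replicate 3 against 8.69 to 10.14 elsewhere, and a difference of -0.39 without that array. AKINBETA1, a subunit of the SnRK1 energy-sensing kinase, had 10.72 ± 0.40 in mock and 9.97 ± 0.22 in G3P leaves (SD, n = 3 each), a difference of -0.75 ± 0.26 (SE). It passed when adjusted over the list alone (limma, adjusted p = 0.0402 over 2 sugar-response genes) and did not pass over all probe sets. Here, too, the adjustment takes no account of the other lists. APL3, the other member, had 0.16 ± 0.29. The fatty acid thioesterase genes FATB and FATA1 had -0.33 ± 0.23 and -0.25 ± 0.39. Differences of the others were 0.37 ± 0.25 for UPOX and 0.30 ± 0.66 for GSTU25 (oxidative stress), 0.56 ± 0.45 for HSP15.7 and 0.21 ± 0.29 for ROF2 (heat shock), -0.21 ± 0.17 for the ethylene-signalling factor EIN3, and 0.44 ± 0.26 for the glucosinolate gene BCAT4. Guard cell and epidermis markers FAMA and GASA9 had 0.04 ± 0.29 and -0.18 ± 0.50. Without G3P replicate 3 the differences were -0.06 for APL3, -0.14 for FATB, 0.13 for FATA1, -0.37 for GSTU25, 0.11 for ROF2, 0.22 for BCAT4 and 0.33 for GASA9, while HSP15.7 had 0.07 without mock replicate 1 and FAMA -0.22 without mock replicate 3. Lists for phosphate starvation, senescence, phenylpropanoids and flavonoids, lipid transfer proteins, flower, root and meristem, and vasculature had 0 members with a named probe set. Their genes may be among the unnamed probe sets. PR1, DIR1, AZI1, EARLI1, GLY1, GLI1 and FAD7 had no named probe set and were not analysed here.

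One array stood apart from the others. G3P replicate 3 correlated at 0.842 to 0.913 with the other arrays across probe sets, which are not independent replicates, and the other 5 at 0.930 to 0.961 among themselves. It held 1223 probe sets over 1 log2 unit outside the range of the other 5 arrays, 609 above and 614 below, against 42 to 186 on each other array. Among the list members, BSMT1, PDF1.2A, JMT, SARD4, GRX480, WRKY6, WRKY53, GSTU25 and GH3.3 lay above that range on G3P replicate 3. DIR1-like, GPDHC1, GPDHP, LLP1, LHCB4.2, PSAN, GI, COR15B and IAA29 lay below it. Without this array 0 probe sets passed and 437 had an unadjusted p under 0.05 (limma).

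**Figure D3:**
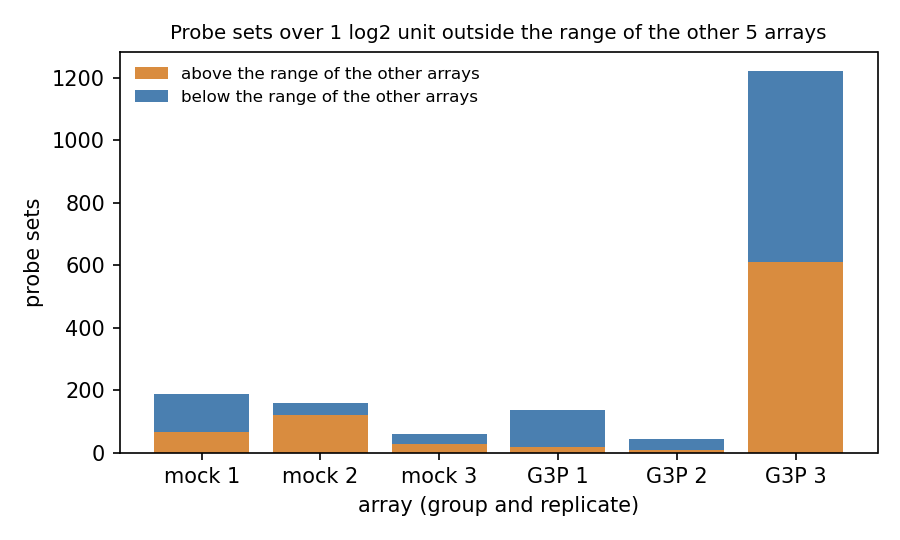
Number of probe sets (vertical axis) on each array, by group and replicate, whose log2 signal lay over 1 log2 unit above or below the range of the other 5 arrays. G3P replicate 3 has 1223 such probe sets and the next array, mock replicate 1, has 186.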

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

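Leaving out G3P replicate 3 together with mock replicate 2, the counts at an unadjusted p, and the gene families with all of their alternatives were chosen after the data were seen. The count of 0 probe sets past the adjusted threshold, in both directions, held under all 11 other fits of the 6 arrays with limma, with each array left out in turn and with both arrays left out. The exact rank-sum test also gave 0, but with 3 against 3 its p cannot go below 0.1, so it could give no call and says nothing about stability. The smallest adjusted p ranged from 0.114 with array quality weights to 0.9996 without mock replicate 1 (0.242 in the main analysis). The count at an unadjusted p under 0.05 was 496 of 16129 probe sets, 517 after quantile normalization, 716 with array weights and 335 with both arrays left out, and it ran from 233 without mock replicate 1 to 1196 without G3P replicate 2. Fewer arrays give each fit less power, and the cause of the rise without G3P replicate 2 was not tested.

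The replicate number as a block gave 0 probe sets, 685 at an unadjusted p under 0.05 and a smallest adjusted p of 0.676. The block was kept out of the main fit because nothing in the sources says that the numbers mark shared plants. The deviations of same-numbered arrays from their group means correlated at 0.0061, -0.102 and 0.314 for numbers 1, 2 and 3. Mock replicate 1 correlated best with G3P replicate 2 (0.451), mock replicate 2 with G3P replicate 1 (0.080) and mock replicate 3 with G3P replicate 3. Deviations within a group of 3 sum to 0 and so are tied, and these values cannot decide whether the numbers pair the plants. With the block 4 gene lists passed, the cold and abscisic acid list being added (adjusted p = 0.0428), and 2 gene families, the plastid-encoded NADH dehydrogenase-like genes being lost; no other call changed.

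The count of gene lists past the threshold was 3. It was 0 with an estimated correlation and 1 without the dimmest 25% of probe sets, where fewer genes were tested and jasmonate and auxin no longer had enough members, and it ran from 0 without mock replicate 3 to 3 with single arrays left out (1 without G3P replicate 3). The count of gene families was 3, 0 with an estimated correlation, 1 after quantile normalization, and from 1 without G3P replicate 3 to 7 without G3P replicate 1. The cause was not tested.

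Of 1245 recomputed differences of the named genes, 1185 kept their direction and side of the threshold and 60, over 23 genes, changed sign, none of them past the threshold in any setting. Of these, 438 belong to the 24 genes chosen for non-overlapping groups, whose sign leaving out arrays or taking medians cannot turn, so their count says nothing about stability. EIN3, COR47, GH3.5, AKINBETA1, AUR1 and TIP41 are bound in the same way, since their groups do not overlap either. The replicate block, the changes to the variance trend and the filters on probe sets leave a difference as it was, so they could turn no sign. The count of 1185 is therefore no measure of stability. The log2 differences with changed sign were -0.47 for GRX480, 0.069 for GPDHP, 0.38 for AZI3, 0.058 for GPDHC1, 0.074 for FATA1, -0.31 for ZAT10, -0.17 for GSTU25, 0.022 for GASA9 and -0.0070 for UBC21 with array weights. The ratio of medians was taken on signals without the pseudocount, so the size of its values cannot be set beside the others. Dim probe sets such as that of BSMT1 can give large ratios. By this ratio the log2 differences with changed sign were -0.48 for GRX480, 0.0016 for SAG101, 0.24 for DIR1-like, 0.19 for GPDHP, 0.37 for GPDHC1, 0.27 for FATA1, -0.095 for JMT, -1.22 for BSMT1, -0.20 for WRKY6, -0.87 for GSTU25, -0.11 for FAMA and -0.028 for UBC21. With G3P replicate 3 and mock replicate 2 both left out they were 0.46 for DIR1-like, 0.11 for GPDHP, 0.55 for GPDHC1, -0.31 for BSMT1, -0.18 for THI2.1, 0.019 for COR15B, -0.11 for WRKY6, -0.24 for GSTU25, 0.0073 for PSAN, -0.12 for APL3, -0.73 for GH3.3 and 0.37 for GASA9. After quantile normalization that of UBC21 was -0.025. With single arrays left out the differences ran from -0.52 to 1.2 for GRX480, -0.33 to 0.20 for SAG101, -1.61 to 0.47 for DIR1-like, -0.63 to 0.20 for GPDHP, -1.32 to 0.39 for AZI3, -0.72 to 0.48 for GPDHC1, -0.45 to 0.13 for FATA1, -0.29 to 3.26 for BSMT1, -1.13 to 0.039 for COR15B, -0.15 to 0.89 for WRKY6, -0.017 to 1.65 for ZAT10, -0.49 to 0.033 for WRKY22, -1.19 to 0.37 for WRKY53, -0.37 to 0.74 for GSTU25, -0.058 to 0.38 for APL3, -0.35 to 2.37 for GH3.3, -0.16 to 1.02 for AUR2, -0.73 to 0.33 for GASA9, -0.22 to 0.21 for FAMA and -0.14 to 0.13 for UBC21. The cause was not tested, but 12 of the genes turned when G3P replicate 3 was the array left out. Signal over background is not analysed here, so dim probe sets were limited only by the pseudocount and by the filters on mean signal.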

Other observations

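The gene families, the limit for values outside the range, the tests of a jasmonate-type response and of a stronger treatment effect, and the counts of splits for probe sets were chosen only after the results had been seen. Among 29 families defined by gene symbols, 3 passed with the preset correlation (camera, limma) and 0 with an estimated correlation, and no member of a family passed over all probe sets. TRM genes, whose products recruit proteins to the cortical microtubule array, were lower in G3P leaves, with 8 of 8 members negative (adjusted p = 0.0259, and adjusted p = 0.636 with an estimated correlation). TRM22 had a log2 difference of -1.22 ± 0.45 (SE) and TRM20 one of -1.10 ± 0.52 (-1.66 to -0.81 with 1 array left out). The median of the family against the other arrays was 0.43, 0.31 and 0.32 on the mock arrays and -0.44, 0.16 and -0.55 on the G3P arrays. The call was lost without mock replicate 3 (adjusted p = 0.0659) or G3P replicate 3 (0.072).

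ATG8 genes, which encode the ubiquitin-like proteins of autophagosomes, had 9 of 9 members positive (adjusted p = 0.0424, and adjusted p = 0.636 with an estimated correlation), such as ATG8G with 0.62 ± 0.44 (SE) and ATG8E with 0.61 ± 0.37 (0.25 without mock replicate 1 and 0.36 without G3P replicate 1). The family's median against the other arrays was -0.56, -0.33 and 0.34 on mock replicates 1, 2 and 3 and 0.53, -0.20 and 0.22 on G3P replicates 1, 2 and 3. These signs part mock replicates 1 and 2 and G3P replicate 2 from the other arrays, a split described below, and not the treatment groups. The call was lost after quantile normalization (adjusted p = 0.105) and without mock replicate 1 (0.348), mock replicate 2 (0.206), G3P replicate 1 (0.454) or G3P replicate 3 (0.072). Plastid-encoded subunits of the NADH dehydrogenase-like complex had 7 of 10 members positive (adjusted p = 0.0424, and adjusted p = 0.636 with an estimated correlation), led by ndhE and by ndhG (0.70 ± 0.27). Their median was -0.50 on mock replicate 3 and 0.48 on G3P replicate 1, and between -0.074 and 0.054 on the other 4 arrays. The rise on G3P replicate 1 was not particular to these genes. Plastid-encoded photosystem, cytochrome b6f and ATP synthase, and ribosomal protein genes had medians of 0.42, 0.51 and 0.56 there. On mock replicate 3 these had -0.05, -0.09 and -0.16. The call was lost without mock replicate 3 (adjusted p = 0.279) or G3P replicate 1 (0.464), after quantile normalization (0.0646) and with the replicate block (0.0528).

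On G3P replicate 3, 8 of 33 UDP-glycosyltransferase genes lay above the range of the other arrays, against 263 of the background of 8854 genes (Fisher's exact test, 1-sided, adjusted over 29 families in each direction, adjusted p = 0.00023). This test rests on 1 array and takes the genes of a family as independent, which they need not be, so its p-values here and below can be too small and show nothing beyond this array. UGT76E12 stood at a log2 signal of 10.15 against at most 6.47 and UGT76B1 at 9.35 against at most 6.33. No other family passed above the range, the nearest being beta-glucosidases with 3 of 13 genes (adjusted p = 0.0689) and defensins (adjusted p = 0.118). Of single genes, chosen after their values were seen, the chitinase gene CHI (AT2G43570) stood at 12.42 against at most 8.22 and the calmodulin-like gene CML41 at 12.13 against at most 8.79. Below the range were 5 of 17 expansin and xyloglucan enzyme genes (adjusted p = 0.00407) and 3 of 6 GH9 endoglucanase genes (adjusted p = 0.0114), with EXPA8 at 6.08 against at least 10.74 on the other arrays. PORB, an enzyme of chlorophyll synthesis, stood at 10.10 against at least 12.95, and STOMAGEN, a peptide that promotes stomatal development, at 7.11 against at least 9.71. Mock replicate 2 held other genes above the range, among them EXO (12.88 against at most 9.90), CML38 (12.53 against at most 10.42), CML37, PUB22 and PUB23. On G3P replicate 1 the jasmonate-responsive factor gene ORA47 stood at 12.38 against at most 10.17.

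Why G3P replicate 3 stood apart was weighed with 3 tests. A difference in overall signal distribution is argued against, since after quantile normalization the array still held 6.94 times as many probe sets outside the range as the next array. A jasmonate-type wound or defence response in these plants stays open. The fixed jasmonate list had a median rise of 2.70 on this array, at percentile 100 of 10000 random lists matched on mean signal, but members of this list had been seen to be high there before the test was written, so the percentile does not count for that explanation. Of the salicylic acid and systemic acquired resistance list, 2 of 4 members lay above the range on this array and 1 below it. Of the pattern-triggered immunity list, 2 of 6 lay above and 0 below. The test therefore cannot tell a jasmonate-type response from another kind of defence response. Whether the G3P treatment acted more strongly in these plants cannot be told apart from a cause unrelated to it, because over the 609 probe sets above the range G3P replicates 1 and 2 exceeded mock by a median of 0.0080, and the highest of the other 9 pairs of arrays gave 0.252. A mislabelled or separately handled sample was not tested.

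A split of the 6 arrays that does not follow treatment gave the most probe sets at an unadjusted p under 0.05. Mock replicates 1 and 2 with G3P replicate 2, against mock replicate 3 with G3P replicates 1 and 3, gave 2477, and the split by treatment gave 496. Unequal signal distributions are argued against as the whole cause, since 2385 were found after quantile normalization (at most 907 in another split), and so is G3P replicate 3 alone, since 2260 were found without it (at most 1670 in another split of those 5 arrays). What the split reflects stays open, because it was picked as the highest of 10, 0 of its probe sets passed after adjustment, and no biological explanation was tested.

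With 10 splits of 3 against 3 no share under 0.05 can be reached, so the splits are too few to tell. The number of probe sets past the adjusted threshold was 0 for the treatment and at most 0 in the other splits; 10 of 10 splits give at least 0 by construction, so this count decides nothing. At an unadjusted p under 0.05, 6 of 10 splits gave as many as the 496 of the treatment, the highest of the others being 2477. For gene lists 3 of 10 splits gave as many as the 3 of the treatment, with 6 the highest of the others, and for gene families 8 of 10 gave as many as the 3 of the treatment, with 9 the highest of the others.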
